A study of Mus musculus with 2 samples.

How the data were processed

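DNase-seq was read from 2 libraries of mouse adrenal gland, biological replicates 1 and 2 of 1 group. Both pools were labelled female, aged 14 days, of strain B6CASTF1/J, with the same donor entry, and the label of each named 3 females. The instrument models named were the same for both. Labels gave no batch, condition or treatment, so the comparisons made were between the replicates, between gene lists and random lists, and between regions of the genome.

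Each library came with 2 peak lists, a list of bases with a false discovery rate and a list of footprints, all on mm10 per the labels. The peak signal was deposited per library after the authors had called peaks on filtered alignments. Every signal value under 100 steps was a whole multiple of 1 step per library (100% of values, tolerance 0.02 counts), so the signal was read as a count scaled to a library total. The window behind the signal was not stated. The deposited FDR values came per stretch of bases, and only stretches at or below 0.05 were listed. The footprint lists carried the same deposited FDR of 0.01 for every footprint. The aligner, the peak caller and the footprint caller were not given in the sources used here. In each library every peak of the longer list held a base with an FDR under 0.05 and every peak of the shorter list held one under 0.001, so the longer list was used throughout and the shorter as a stricter alternative. It held 145192 peaks in replicate 1 and 95492 in replicate 2. Called regions were the merged bases listed at an FDR of 0.05 or below, 347459 and 226803 of them, and stood in for a separate region file.

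Genes and transcription starts came from GENCODE M21 basic and sequence from GRCm38.p6, the same assembly as mm10. Of the peaks, 0 ran past a chromosome end. Chromosome Y genes were left out of the gene tests, since the pools were labelled female. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

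Peaks counted as shared when they overlapped by at least 1 bp. The intervals of shares were Wilson 95% intervals. For the level reached by position alone, peaks were shuffled within chromosomes 10 times. Pairs of shared peaks gave a log2 ratio of signals, and the centred ratio subtracted the median over all pairs. Peaks were placed by their middle in promoter, exon, intron or intergenic sequence, in that order, and compared with the bases of the assembled genome other than N.

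The gene lists, motifs, comparisons and most alternatives were fixed before the data were examined. The 19 lists covered steroidogenesis, cortex regulators, chromaffin, endothelial, macrophage, Schwann, capsule, fat, kidney and lymphocyte genes, hepatocyte, striated muscle, photoreceptor and epidermis genes from outside the gland, and gonad, housekeeping, immediate early, cAMP and olfactory receptor genes. A gene's promoter signal was the highest signal of a peak within 500 bp of any of its annotated starts, or 0. The distance of these peaks from a principal start, that of a transcript the annotation tags as principal, was added after the data were seen. Distal peaks lay more than 1000 bp from any start and were given to the protein-coding gene with the nearest start up to 100 kb away. A list's median, on the mean of both libraries, was placed among 10000 random lists of the same size, matched by decile on the CpG ratio of the promoter or on the size of the gene's territory. For the balance of the libraries, the median centred ratio of shared peaks near a list was placed among 10000 random sets of peaks matched by decile on mean signal. Percentiles over 95 or under 5 were treated as calls. For promoters the plan gave this percentile to the median signal and only described the share of genes open in both libraries. The percentile of the share among the same random lists was added to the text after the data were seen and was not treated as a call.

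The 27 motifs were searched on both strands in the central 150 bp of each peak and in windows 1000 bp to each side that lay outside every called region, matched on GC content in bins of 2.5%. Flank ratios of motifs found in fewer than 20 flank windows of either library were left out of the text, a limit chosen after the data were seen. Footprints, with 10 bp on each side, were compared with windows of the same width shifted by 60 bp in the same peaks. A peak held a CTCF core with up to 1 mismatch when CTCF peaks were left out of the balance, and an exact one elsewhere.

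Genes and regions were named by a rule: the list members with the highest promoter signal or the most distal peaks, the 20 autosomal peaks with the highest mean rank, the 20 genes with the most distal peaks in the library with fewer peaks, the 5 shared peaks most different each way among those above the median signal, and the 10 widest called regions by the smaller of their widths in the libraries. List members without a peak were named where 5 or fewer. Some items that the rule names are not reported here. A second fat list, a second kidney list and a list of 4 X-linked genes known to escape inactivation were written before their tests but after the first results. Whether a promoter peak also lay within 500 bp of another gene's start was looked at after the data were seen. Other members of the lists were chosen after their values were seen, as were Ptprc, Csf1r and Spi1, the 4 X-linked escape genes and the strongest Y peaks.

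The list test, the overlap count, the motif count and the shuffle were tested on simulated data, with planted effects recovered and null lists called at about the nominal rate. The simulated values were independent between genes. Peaks near the same gene need not be, so this rate was not tested for the balance or for motifs by gene list. Alternatives were a stricter FDR, peaks above the median signal, lists of equal length, a larger overlap, called regions, a promoter window of 1000 bp, no CpG matching, a reach of 20 kb, a window of 100 bp, a shuffled background, distal or proximal peaks, ranks, peaks without a CTCF core, and each library alone. An outlier test, a paired analysis and a regrouping of samples did not apply to 2 libraries of 1 group. Counts of cuts per region were not analysed here, since the files held false discovery rates. The share of footprints above a stricter score could not be computed, as the score was constant.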

Results

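Open chromatin was mapped by DNase-seq, which reads where the nuclease cuts accessible DNA, in adrenal glands of female mice aged 14 days. The animals were B6CASTF1/J hybrids. The 2 libraries, called replicate 1 and replicate 2 as in the labels, were biological replicates of 1 group, and the label of each pool named 3 females. The labels stated no question beyond the mapping itself. Replicate 1 had 235793 peaks and replicate 2 had 153523, with a median peak width of 180 bp in each. The depth itself was not stated. The signal values were whole multiples of a single step per library, as counts scaled to a library total would be, and implied totals of 249.353 M and 125.354 M. This is an inference from the values. On that reading the median peak rested on 146 and 98 counts. Peaks and genes are placed on mm10 with coordinates counted from 1. Errors after ± are SD over the 2 libraries (n = 2). No p-values were computed. A percentile places a list among 10000 matched random lists and describes these libraries alone.

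The first comparison asked how far the replicates shared their open regions. The strongest shared autosomal peak by rank, at chromosome 1 from 88277521 to 88277740, lay at the start of Hjurp, which loads the centromeric histone, with signals of 70.7 and 51.6. The next lay at Dynlt1b, a dynein light chain gene, at chromosome 17 from 6430021 to 6430180, with 64.4 and 67.2. Peaks at the starts of Eif5a, Nup107 and Bahcc1 had mean signals of 41.3, 40.6 and 40.0. One of the 20 strongest, at chromosome 17 from 39846781 to 39846900, overlapped an annotated ribosomal RNA gene, where repeated sequence makes mapping uncertain. Of the replicate 1 peaks, 56.5% overlapped a replicate 2 peak (Wilson 95% interval 56.3 to 56.7). In the other direction the share was 86.5% (86.3 to 86.7). Shuffled peaks overlapped at 3.42%. These intervals cover counting error only.

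Sharing followed signal. In replicate 1 it ran from 9.62% in the weakest signal decile to 98.9% in the strongest, and in replicate 2 from 46.9% to 99.8%. The 102578 peaks of replicate 1 alone had a median signal of 0.345, against 1.07 for its shared peaks. The 20745 peaks of replicate 2 alone had 0.343, against 0.901. Across 131618 shared pairs the signals had a Spearman correlation of 0.855, taken across peaks, which are not independent replicates. The log2 ratio of replicate 1 to replicate 2 had a median of 0.23 and an SD of 0.69.

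**Figure D1:**
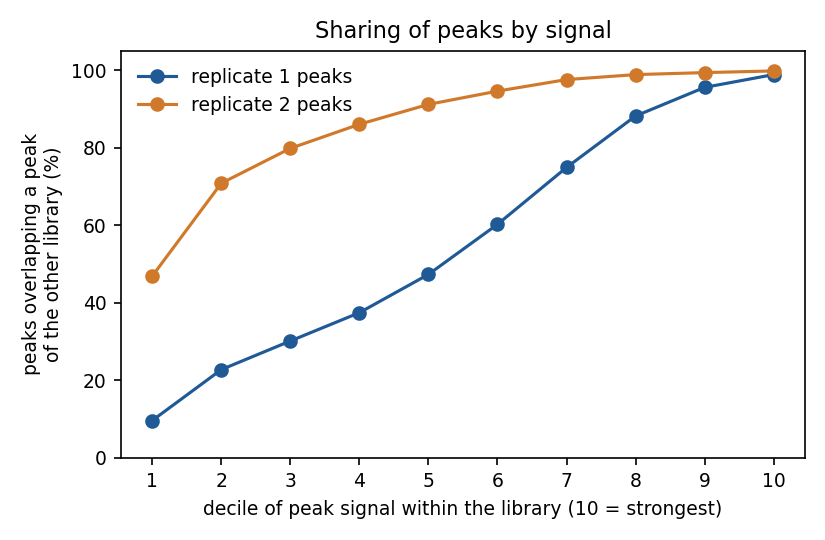
Share of each library's peaks (y axis, percent) that overlapped a peak of the other library, by signal decile (x axis, 1 weakest to 10 strongest), with a line per library. The share reached 98.9% for replicate 1 and 99.8% for replicate 2 in the strongest decile.

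Promoters, from 1000 bp before to 100 bp after a transcription start, held 12.5% of replicate 1 peaks and 15.6% of replicate 2 peaks, in 2.54% of the assembled genome. Introns held 46.7% and 44.8%, against 41.2% of the genome. Exons held 8.09% and 7.65%, against 3.57%. Intergenic sequence held 32.8% and 32.0%, against 52.7%. Promoter peaks were the strongest class, with median signals of 2.06 and 2.61, while intergenic peaks had 0.469 and 0.622. Among peaks above the median signal the mean promoter share was 21.4%, against 14.0% among all.

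Called regions were ranked by the smaller of their widths in the libraries. The first covered 10566 bp in replicate 1, at chromosome 8 from 70751970 to 70762535, and 7242 bp in replicate 2. It overlapped Rab3a, a regulator of vesicle release, and Mpv17l2, and held 18 and 16 peaks. The next by this rank covered 4885 and 4859 bp at Brd2, a reader of acetylated histones. A region near Crlf2 covered 7283 bp in replicate 1 but 4288 bp in replicate 2. Regions at the transcription factor genes Myc and Jun spanned 4404 and 4255 bp in replicate 1. Tns1, which encodes a focal adhesion protein, had 150 and 79 distal peaks assigned to it, the most of any gene in replicate 2. Pde4d, a cAMP phosphodiesterase, had 94 and 69, and Zbtb20 and Zfp423, which encode transcriptional regulators, had 58 each in replicate 2.

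The promoters of the adrenal's own genes were compared with those of other cell types. Of 24 genes for steroid synthesis and cholesterol supply, 22 had a promoter peak in both libraries, 91.7% against 62.0% in CpG-matched random lists (percentile 100 of the share). The strongest were Por, the electron donor of microsomal P450 enzymes, at 23.6 ± 1.94, and the cholesterol exporter of lysosomes Npc1 at 23.6 ± 4.37. Fdxr, which feeds electrons to mitochondrial P450 enzymes, had 18.8 ± 3.21, and Stard4, of cholesterol transport, had 14.5 ± 0.423. Star, which carries cholesterol into mitochondria, had 3.75 ± 1.17. The side-chain cleavage enzyme gene Cyp11a1 had 3.15 ± 0.558, and Cyp21a1 had 3.32 ± 0.0636. The corticotropin receptor gene Mc2r had 0.556 ± 0.0940. The list's median of 8.09 stood at percentile 99.9 of CpG-matched random lists, whose mean was 2.32. Por, Npc1, Fdxr and Stard4 lay above this median, while Star, Cyp11a1, Cyp21a1 and Mc2r lay below it. The percentile thus describes the list as a whole and does not show strong promoters at the latter genes. Hsd3b1 and Cyp11b2 had no promoter peak in either library. These genes, Cyp11b1, Hsd3b6 and Cyp21a1 have close copies in the genome and mapping there is uncertain.

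Regulators of cortex identity and zonation had a promoter peak in both libraries at 25 of 26 genes, with Pik3c2g open in replicate 1 alone. At Thrb, Lef1 and Ptch1 the peak lay more than 500 bp from a principal start, that of a transcript the annotation tags as principal. Without these 22 of 26 were open in both, a count not made for random lists. The share of 96.2% lay above the 87.0% of random lists (percentile 95.9). Nr4a1, a nuclear receptor induced by corticotropin, had 17.7 ± 5.85. The Wnt pathway genes Znrf3 and Axin2 had 14.0 and 12.9, and the coactivator gene Cited2 had 13.7. Nr5a1, which encodes SF1, the main regulator of steroid cells, had 6.17 ± 1.40. The list's median signal of 3.91 lay below the random mean of 7.01, at percentile 3.79, so share and signal lay on opposite sides. Without matching on CpG content the percentile was 65.2, on the other side of the middle.

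Genes of the catecholamine-making chromaffin cells of the medulla were open in both libraries at 23 of 25 promoters (percentile 93.5 of the share). Ddc, the decarboxylase of dopamine synthesis, had no peak, and Pnmt, which makes adrenaline, was open in replicate 1 alone. Th and Dbh, which act earlier in that pathway, had 1.37 ± 0.147 and 1.69 ± 0.00366. Slc18a1, a vesicular amine transporter gene, had 21.7 ± 2.39, yet its peak also lay at the start of Atp6v1b2. The granule protein genes Chgb, Scg2 and Chga had 9.34, 4.88 and 3.76, and Gata2 had 5.73. The list's median of 1.37 lay at percentile 0.28, against a random mean of 5.58. Without CpG matching it lay at percentile 21.9.

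Among other cell types of the gland, endothelial genes were open at 18 of 18 promoters, against 71.35% in random lists, a share at percentile 99.985. They were led by Ets1 at 12.4 ± 1.09 and the receptor gene Kdr at 3.26 ± 0.316, and their median signal lay at percentile 19.6. Fat genes were open at 11 of 12, against 55.2%, a share at percentile 99.9, led by the adipocyte factor Cebpa at 14.8 ± 1.76. Cidea had 5.07 ± 0.266 and Ucp1, the heat-producing uncoupler of brown fat, had 3.19 ± 1.44. Their median signal lay at percentile 91.7, and at 97.0 in replicate 2 alone. Capsule and fibroblast genes were open at 10 of 12, against 49.6%, led by Pdgfra at 5.72, with the share at percentile 99.8 and the median signal at 79.8. Schwann cell genes were open at 8 of 12, with the share at percentile 52.8 and the median signal at 21.2. Macrophage genes were open at 5 of 16, 31.2% against 32.0% in random lists, with the median signal at percentile 79.2. They had Irf8 at 7.5 and no peak at Ptprc, Csf1r or Spi1. Kidney genes were open at 4 of 14, with the share at percentile 4.77 (19.4 without replicate 2) and the median signal at 13.3, led by Aqp2 at 0.750. Their median signal was 0, so its percentile reflects only how many random lists also had a median of 0. Lymphocyte genes were open in both at 0 of 12, against 31.5% in random lists, a share at percentile 0.075, but 8 were open in replicate 1 alone and 1 in replicate 2 alone. Without replicate 2 the share lay at percentile 98.2, so this result turned on the library. Their median signal lay at percentile 86.7, and at 43.9 without replicate 1, where it was 0 as in many random lists.

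Of the lists for tissues outside the gland, 0 of 15 hepatocyte genes and 2 of 14 photoreceptor genes were open in both libraries. Their shares lay at percentiles 0.005 and 1.28 of random lists. In addition 1 hepatocyte gene was open in replicate 1 alone and 1 in replicate 2 alone. Epidermis genes were open at 2 of 12, a share at percentile 5.12. Striated muscle genes were open at 5 of 14, 35.7% against 36.1% in random lists, a share at percentile 49.3. The median signals of hepatocyte, muscle, photoreceptor and epidermis genes were 0 and lay at percentiles 37.3, 25.8, 21.3 and 29.6. No random list could lie lower, so these percentiles reflect only how many random lists also had a median of 0. The strongest genes of these lists were Krt10, an epidermal keratin gene, at 10.1, from a peak 3184 bp from a principal start, and Rom1, a photoreceptor membrane gene, at 9.30, whose peak also lay at the start of Eml3. Gonad genes were open at 6 of 14, led by the germ cell gene Dazl at 12.3, 696 bp from a principal start. Their share lay at percentile 4.34 and their median signal, also 0, at 0.67. Housekeeping genes were open at 18 of 18, with the share at percentile 78.6 and the median signal at 99.9. Immediate early genes were open at 16 of 16, led by Klf6 at 29.1 ± 1.24 and Jund at 23.4 ± 1.63, with the share at percentile 71.1 and the median signal at 92.6. Genes of cAMP signalling were open at 15 of 16, led by Crtc1 at 22.4, with the share at percentile 19.2 and the median signal at 36.5. Olfactory receptor genes were open at 27 of 1133, 2.38% against 16.5% in random lists, a share at percentile 0. Their median signal of 0 equalled that of the random lists, which gives percentile 50. Without CpG matching the macrophage, kidney, hepatocyte, muscle, photoreceptor and epidermis median signals lay at percentiles from 0.89 to 1.84, olfactory receptors at 0, fat at 41.1, immediate early at 99.9 and cAMP genes at 98.0. With a window of 1000 bp immediate early genes lay at 96.7. In replicate 1 the peak lay more than 500 bp from a principal start at 3 cortex genes, 2 each of the endothelial, kidney and cAMP lists, 1 each of the Schwann, fat, muscle, epidermis, gonad and immediate early lists, and at 0 in the other lists, with olfactory receptors left out of this count. The share of all 21644 protein-coding genes open in both libraries ran from 6.00% in the lowest CpG decile to 98.8% in the highest.

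**Figure D2:**
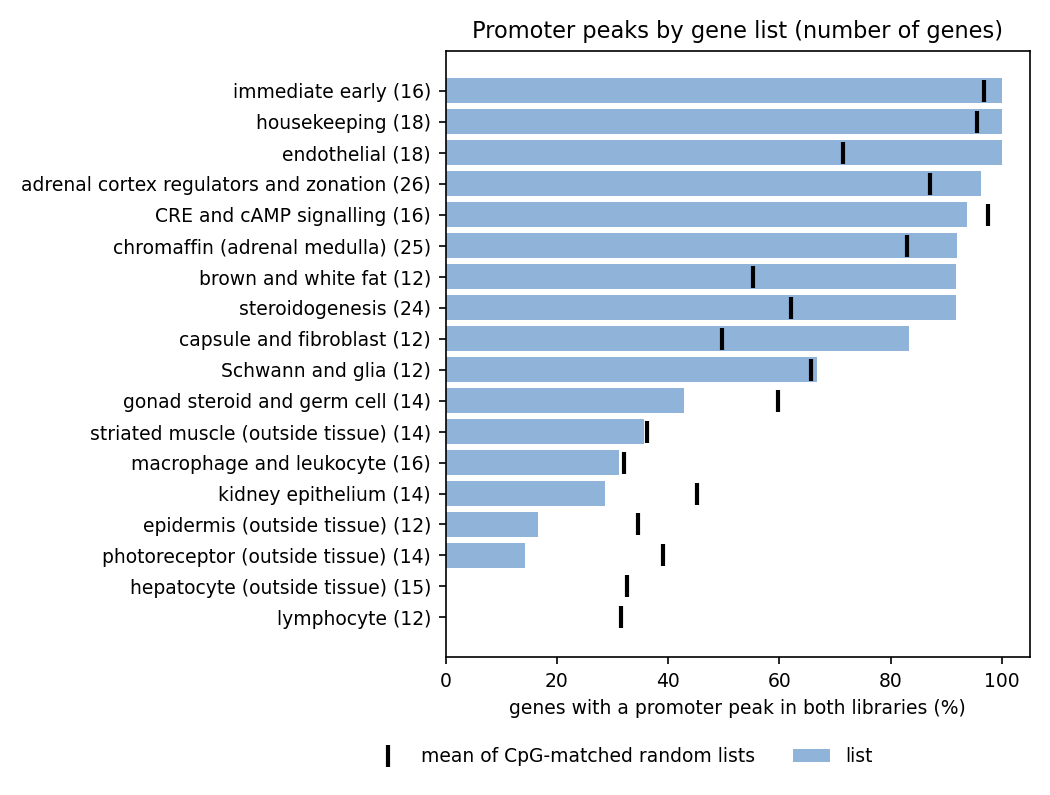
Share of each fixed gene list other than olfactory receptors (bars, x axis in percent, number of genes in brackets) with a promoter peak in both libraries, and the mean share in CpG-matched random lists (black marks). Steroidogenesis stands at 91.7% against 62.0%, and hepatocyte genes at 0% against 32.6%.

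Distal peaks, more than 1000 bp from any transcription start, gathered around cortex genes. Axin2, a target and brake of Wnt signalling, had 73 and 33 in replicates 1 and 2. Scarb1, the receptor that takes up cholesterol from lipoproteins, had 52 and 24, and Cyp11a1 had 38 and 11. Dlk1, found in the outer cortex, had 45 and 16, and Gata6 had 36 and 24. Steroidogenesis genes had a median of 10 distal peaks, against 3.93 in random lists of like territory (percentile 100). Cortex regulators had 14.8 against 7.97 (percentile 99.9). Chromaffin genes had 6.5 against 6.74 (percentile 47.7, but 94.1 within 20 kb), although Chga had 35 and 21.

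Immediate early genes had a median of 15.0 distal peaks (percentile 100), with 41 and 20 at Fos. Endothelial genes had 12.8 (percentile 99.98), with 34 and 24 at Kdr, and genes of cAMP signalling had 12.8 (percentile 99.4). Fat genes had 9.50 (percentile 99.5), with 30 and 20 at the leptin gene Lep. Schwann and capsule genes lay at percentiles 90.6 (95.9 within 20 kb) and 80.7, and macrophage and kidney genes at 49.98 and 14.9. Hepatocyte, muscle and photoreceptor genes lay at 70.9, 28.2 and 83.8, and epidermis genes at 1.02 (20.5 without replicate 1). Lymphocyte, gonad and housekeeping genes lay at 63.8, 70.1 and 79.6, and olfactory receptors, with a median of 0, at 0. A peak was given to the nearest gene, which need not be the gene it acts on.

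Sequence motifs of transcription factor families were counted in the central 150 bp of peaks. In distal peaks the CTCF core, bound by the factor that anchors chromatin loops, was the most enriched over GC-matched flanks, at a log2 ratio of 6.10 ± 0.19. NFI, HNF1, RFX, COUP-TF and YY1 sites stood in too few flank windows to be ranked in distal peaks. Of the others, AP-1, the motif of Fos and Jun proteins, followed over flanks at 2.01 ± 0.00 and stood in 9.53% of distal peaks. The SF1 site stood in 5.13% of distal peaks against 1.96% of flanks, a log2 ratio of 1.39 ± 0.04. The cAMP response element had 1.59 ± 0.01, the steroid response element 1.40 ± 0.03 and the NUR77 site 1.35 ± 0.20. TEAD and GATA sites had 0.59 ± 0.04 and 0.51 ± 0.00, and the PHOX2 site of the sympathetic lineage had 0.23 ± 0.33. Of the motifs fixed as controls for other tissues, CRX had -0.06 ± 0.12, OCT 0.22 ± 0.09 and p53 0.16 ± 0.01. MEF2, also fixed as such a control, had 1.73 ± 0.28, a mean above those of the cAMP element, the steroid element and SF1. As a control it thus failed, so a ratio of this size alone does not mark a motif of the gland. HNF1, the remaining control, was among the motifs not ranked. Whether MEF2 factors act in this gland was not tested, so the MEF2 value does not show enrichment for another tissue either. Against shuffled sequence CTCF had 5.18, MEF2 2.56, SP/KLF 2.49, the cAMP element 2.46 and SF1 2.04. AP-1 had 1.49 there, below each of these.

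In peaks within 1000 bp of a transcription start, CTCF and NRF1 sites stood in too few flank windows to be ranked there. Of the others, ETS and NFY sites had log2 ratios of 3.70 ± 0.75 and 3.36 ± 0.61, and the cAMP response element had 2.57 ± 0.39. SP/KLF sites had 1.03 ± 0.19, AP-1 had 1.36 ± 0.11 and SF1 had 0.54 ± 0.05. The order depended on the background. Against shuffled sequence the ratio was 4.24 for the cAMP element, 3.46 for ETS, 2.95 for NFY, 2.41 for SP/KLF, 1.29 for SF1 and 0.95 for AP-1. In replicates 1 and 2 it was 3.93 and 4.75 for NRF1 and 3.53 and 3.54 for CTCF. Many proximal peaks had no flank of like GC content and were left out.

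**Figure D3:**
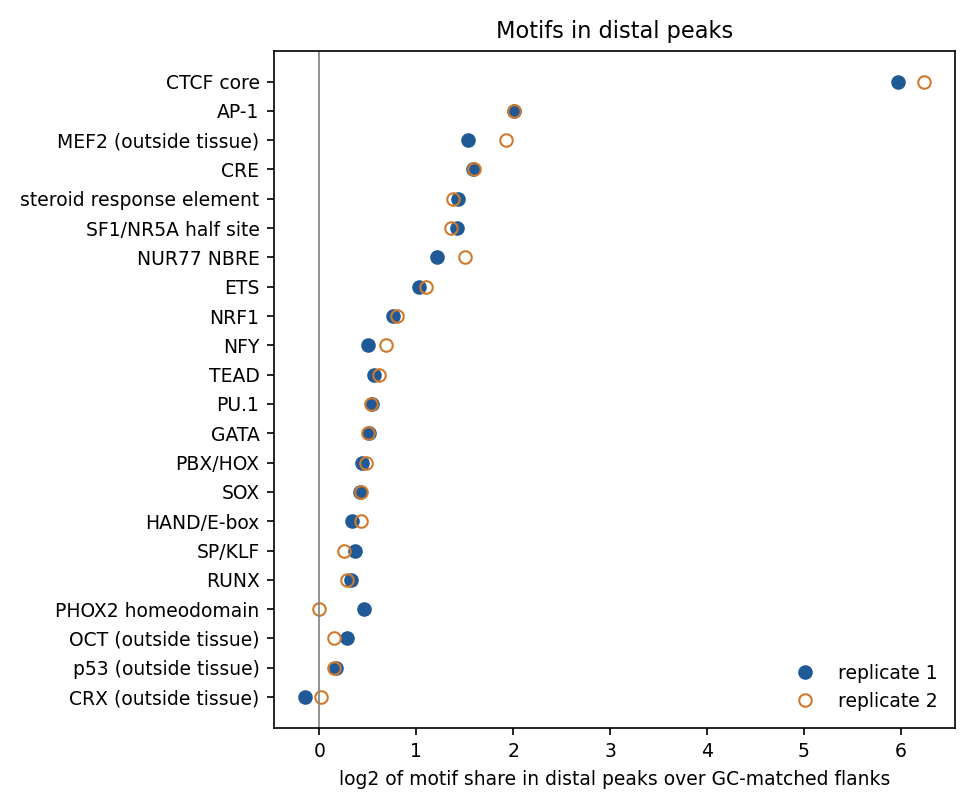
Log2 ratio (x axis) of the share of distal peaks holding each motif to that of GC-matched flanks, with a point per library. Motifs found in fewer than 20 flank windows of either library are not drawn. CTCF lies at 6.10 on average, AP-1 at 2.01 and SF1 at 1.39.

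Footprints, short stretches shielded from the nuclease inside open regions, numbered 502098 in replicate 1 and 289150 in replicate 2, with median widths of 10 and 9 bp. The SF1 site stood in 1.27% of footprints with 10 bp on each side, against 0.715% of windows shifted by 60 bp, a log2 ratio of 0.84 ± 0.02. NFI and RFX sites had 1.25 ± 0.27 and 1.17 ± 0.04 on few sites. GATA and p53 sites had -0.36 ± 0.09 each, below the shifted windows. CTCF differed by library, with 0.21 in replicate 1 and 1.57 in replicate 2. Its share of footprints was 1.48% and 1.76%, and the larger difference lay in the shifted windows, at 1.28% and 0.591%. Shifted windows that met another footprint were not removed, so the low ratio does not show weaker CTCF footprints in replicate 1. Peaks held 89.5% and 91.3% of the footprints. Of footprints inside peaks of both libraries, 46.2% and 62.5% overlapped a footprint of the other, against 34.1% and 43.4% after shifting.

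The sex chromosomes were set against the autosomes, since both pools were labelled female. Chromosome X had 37.9 and 23.6 peaks per megabase, 0.396 and 0.378 of the autosomal density. The median signal of its peaks was 0.578 and 0.596 of the autosomal median. Bcor, an X-linked corepressor gene, still had 86 and 52 distal peaks. Chromosome 11 was the densest autosome, with 143 and 90.1 peaks per megabase, and chromosome 3 the sparsest, with 72.9 and 48.8. Chromosome Y had 81 and 42 peaks, the strongest at 90744501 to 90744820 with a signal of 3.58 in replicate 1. Among peaks above the median signal the mean X density ratio was 0.239, the signal ratio was 1.02 and the mean number of Y peaks was 8. The mean number of Y peaks was 19.5 in the stricter lists and 4 near transcription starts.

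The last comparison asked whether peaks near genes of the gland's cell types were balanced between the libraries. It took the log2 ratio of replicate 1 to replicate 2, centred on all shared peaks. Peaks near fat genes were lower in replicate 1, with a median of -0.54 over 130 peaks (percentile 0 of signal-matched random sets). At Ucp1, 11 of 12 shared peaks were lower, with a median of -1.02, and at Fabp4, a fatty acid carrier gene, 8 of 8 were lower. Not all fat genes followed: Plin1, which coats lipid droplets, had 0.31 with 3 of 8 lower, and Lep had 0.05 with 12 of 24 lower. Of the 11 fat promoters open in both libraries, 10 had the higher signal in replicate 2, against 16.8% of all genes, which were not matched on signal or CpG content. The count was 12 of 19 in a second fat list, 12 of 18 for endothelial genes, 7 of 10 for capsule genes and 14 of 27 for olfactory receptors. These counts were chosen after the data were seen. Peaks near endothelial genes had -0.23 over 190 peaks (percentile 0.01), and those near capsule genes -0.18 over 116 (percentile 3.47, but 11.7 for distal peaks, 9.02 by rank and 13.55 without Col1a1).

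Kidney genes lay the other way, at 0.40 over 51 peaks (percentile 100, but 83.8 near transcription starts), with a median of 0.37 at Pax2, which encodes a factor of kidney development. The tubule transporter gene Slc12a3 did not follow, at -0.53 over 7 peaks. Macrophage genes had 0.35 over 56 peaks (percentile 99.7, but 87.4 near transcription starts). Lymphocyte genes had 0.43 over 25 peaks (percentile 99.95, but 81.0 without peaks that held a CTCF core, 93.2 by rank and 51.7 near transcription starts). Olfactory receptor genes had 0.03 over 307 peaks (percentile 99.95, but 65.2 without CTCF peaks and 19.7 near transcription starts).

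Peaks near steroidogenesis genes had -0.06 over 239 peaks, against 0.10 in random sets (percentile 0.05, but 39.0 near transcription starts). The genes went both ways: of the 20 with 3 or more shared peaks 11 had a positive median, among them Star at 0.26 and Cyp11a1 at 0.16. Abca1, a cholesterol exporter gene, had 27 of 33 peaks lower, and without it the list lay at percentile 0.63 with a median of -0.03. Cortex regulators and chromaffin genes had -0.01 and -0.05, at percentiles 28.3 and 36.8. Without CTCF peaks these were 63.4 and 52.8, and by rank chromaffin genes lay at 90.6. Schwann, housekeeping, immediate early and cAMP genes lay at percentiles 21.3, 10.2, 22.1 and 27.1. Near transcription starts Schwann genes lay at 1.06, and by rank housekeeping genes at 2.44. Hepatocyte, muscle, photoreceptor, epidermis and gonad genes lay at 43.3, 86.3, 33.5, 34.2 and 94.2. Near transcription starts photoreceptor genes lay at 0.08 over 8 peaks, and gonad genes lay at 99.5 for distal peaks. With 1 library on each side, the balance describes this pair of pools.

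**Figure D4:**
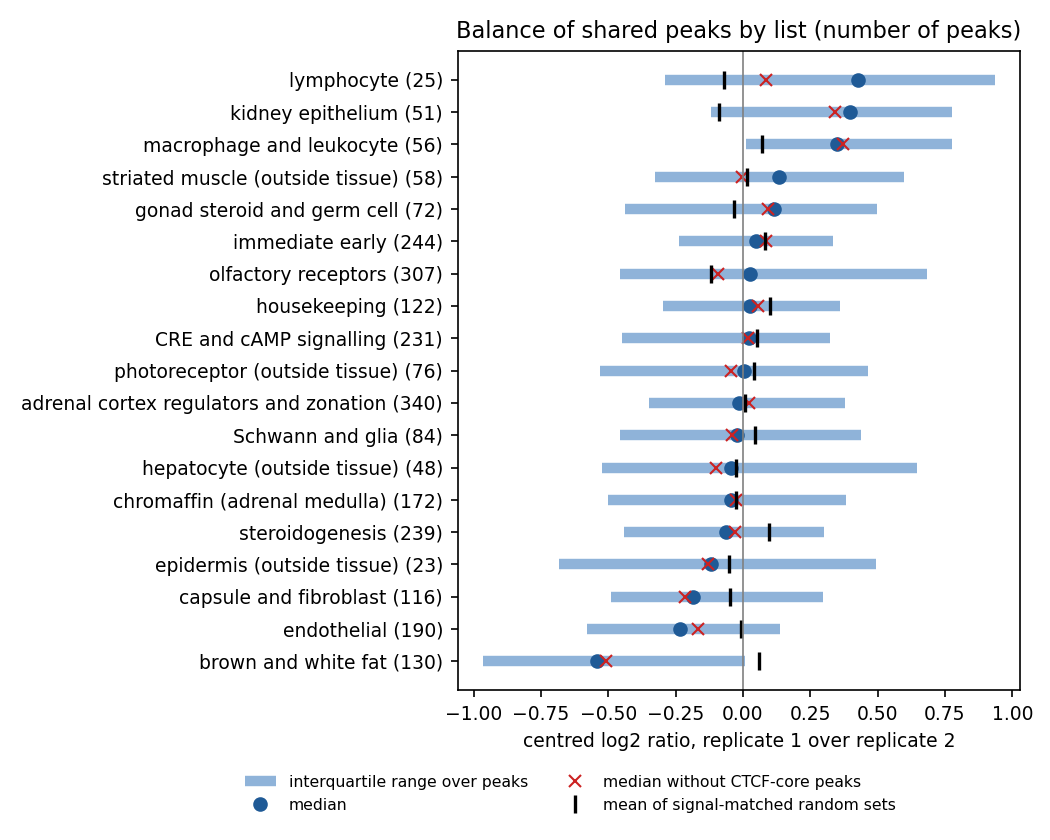
Centred log2 ratio of replicate 1 to replicate 2 (x axis) over shared peaks near each gene list, with medians (points), interquartile ranges (bars), medians without CTCF peaks (crosses) and the mean of signal-matched random sets (black marks). Fat genes lie lowest at -0.54, and lymphocyte and kidney genes highest at 0.43 and 0.40.

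Of single shared peaks above the median mean signal, those most unlike between the libraries lay at the start of the assembled chromosome 9. The peak from 3019081 to 3019207, near Gm10719, had 1.04 in replicate 1 and 36.5 in replicate 2, a centred log2 ratio of -5.36. The peak from 3002461 to 3002620 had 3.77 and 30.4 (-3.24). Whether the sequence at this end of the chromosome is repeated was not tested, so these signals may reflect mapping rather than accessibility. The largest difference the other way was 2.89, at chromosome X from 139416821 to 139417000, with 2.02 and 0.231.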

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

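The alternatives chosen after seeing the data were the stricter list of replicate 1 against the full list of replicate 2, peaks near transcription starts, peaks without a CTCF core, lists with a gene left out, and the stricter lists or single libraries where these were not in the first plan. Of 557 alternatives over 135 results, 439 kept direction and call or stayed within the spread, 85 moved, 16 came to pass the percentile limits, 12 no longer did and 5 reversed. For genomic features, motifs, footprints and the X ratios, a single library always lies within the SD of 2 libraries. Such runs were kept by construction and say nothing of robustness. They made up nearly all of the 55 footprint alternatives, all kept, and many of the kept motif alternatives. The shares of replicate 1 and replicate 2 peaks found in the other library were 49.3% and 75.7% with an overlap of 50% of both peaks, 59.2% and 89.6% in the stricter lists, 74.5% and 74.3% with lists of equal length, and 77.1% and 72.7% with the stricter list of replicate 1 alone. Equal lengths brought the shares together, by construction. The mean promoter share was 10.6% in called regions, 18.8% in the stricter lists and 21.4% above the median signal. These counts leave out the percentiles of promoter shares, which were added after the data were seen. With a window of 1000 bp the share percentile was 93.9 for cortex regulators, 11.4 for photoreceptor genes and 11.4 for gonad genes. Above the median signal it was 10.99 for cortex regulators, 94.8 for endothelial genes and 78.1 for capsule genes. In the stricter lists it was 93.8 for cortex regulators, and with no matching on CpG content it was 87.9 for capsule genes. Without replicate 2 it was 98.2 for lymphocyte genes and 19.4 for kidney genes. Without CpG matching the cortex regulators' promoter percentile reversed to 65.2 and the chromaffin percentile was 21.95. Near transcription starts, the balance percentile of steroidogenesis genes was 39.0 and that of olfactory receptors reversed to 19.7. The distal SF1 log2 ratio was 1.51 in the central 100 bp and 2.04 against shuffled sequence. Against shuffled sequence p53 reversed to -0.10 in distal and -0.30 in proximal peaks, and HAND/E-box to 0.13 in proximal peaks. A motif counted as reversed only where its mean over flanks exceeded its SD. SOX in proximal peaks, at -0.05 with an SD of 0.05 that exceeded it, changed sign to 0.36 and counted as moved. The X signal ratio was 0.568 for distal peaks, 0.573 near transcription starts, 0.714 in the stricter lists and 1.02 above the median signal. A limit on signal removes weak peaks from X and autosomes alike, so it narrows this difference by construction. The X density ratio was 0.364, 0.473, 0.328 and 0.239 in the same order. The mean number of Y peaks was 4 near transcription starts, 19.5 in the stricter lists and 8 above the median signal. Apart from the equal lengths and the signal limit, the cause was not tested. The stricter footprint list of the first plan was not run, as the score was constant. Sharing was lowest among weak peaks, at 9.62% in the weakest decile of replicate 1, and no run at equal depth was made, so what depth limits was not tested. No paired analysis was possible because all libraries belonged to 1 group.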

Other observations

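Tests chosen only after the result was seen were the macrophage test and the kidney tubule promoter test; the search of motifs by gene list and the single-gene balances were also chosen after the data were seen. Distal peaks near genes of cAMP signalling, the pathway that carries the corticotropin signal, held the SF1 site in 21 of 171 cases, 12.3% against 5.16% in signal-matched peaks. Distal peaks near endothelial genes held a SOX site in 5 of 154 cases, 3.25% against 0.454%, and a CTCF core in 0.649% against 5.05%. These were the extremes, at percentiles 99.985, 99.965 and 0.19, of 180 pairs of 18 lists and 10 motifs. Of the 180, 2 lay over percentile 99 and 1 under percentile 1, about what a search of this size gives at the nominal rate. No conclusion is drawn from these pairs. Near steroidogenesis genes the SF1 share was 6.88%, at percentile 84.9, and near cortex regulators it stood at percentile 49.1, so the hypothesis that SF1 sites gather at steroid genes was left undecided for the first and not met for the second.

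CTCF sites stood apart between the libraries. The 4273 shared distal peaks with an exact CTCF core had a median centred log2 ratio of 1.07, higher in replicate 1, while the 289 with a MEF2 site had -0.31 and the 1266 with a NUR77 site -0.17. Near kidney genes, higher in replicate 1, the median without CTCF peaks stayed at percentile 99.99. A second kidney list of 18 genes, of which 0 were in a first list, stood at percentile 90.7, and 0 of 5 abundant tubule genes had a promoter peak in replicate 1.

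Peaks near fat genes were lower in replicate 1, with Cebpa at 14.8, Cidea at 5.07 and Ucp1 at 3.19 as the strongest promoters of the list. Leaving out peaks with a CTCF core kept the list at percentile 0, and restricting it to the stricter peak lists also gave percentile 0, so CTCF peaks and weak peaks are argued against as the whole cause. A lower share of cortex cells in replicate 2 would raise every other type alike. Macrophage genes, at percentile 99.7 (87.4 near transcription starts), went in the opposite direction to fat genes. Endothelial and capsule genes, at 0.01 and 3.47, went with fat genes, as did steroidogenesis genes at 0.05. Chromaffin and Schwann genes lay between, at 36.8 and 21.3. The macrophage test was chosen after its value was seen, so no conclusion on this explanation is drawn from it. More fat tissue around the glands of the replicate 2 pool is a candidate explanation, since a second list of 19 fat genes, with 0 genes in a first list and 19 promoters open in both libraries, stood at percentile 0 with a median of -0.27. This stays a hypothesis, as the fat genes Plin1 and Lep had medians of 0.31 and 0.05, adrenal cells also express some genes of lipid storage and a difference between the animals was not tested.

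Open promoters of chromosome X were weaker than those of autosomes, with ratios of medians of 0.450 and 0.480 in replicates 1 and 2. With autosomal promoters matched on CpG ratio these were 0.581 and 0.649, a mean of 0.615 ± 0.0479 (SD, n = 2) over 471 X promoters. Matching thus removed part of the difference, and what remained argues against fewer CpG-rich promoters on X as the whole cause. Silencing of an X chromosome in females may account for the rest. The 4 genes known to escape inactivation, Kdm6a, Kdm5c, Ddx3x and Eif2s3x, lay above the X median in both libraries, the outcome set for silencing beforehand. They did so unevenly, with ratios to matched autosomal promoters of 2.83 and 3.00 for Kdm6a but 0.75 and 0.64 for Eif2s3x, which lay at percentiles 63.9 and 53.1 of X promoters. Genes with strong promoters would lie above the X median without silencing too, so these 4 genes cannot decide it. A lower output of X genes in both sexes stays open, as these ratios do not separate it from silencing. No male library was analysed here.

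Chromosome Y had 81 and 42 peaks in pools labelled female, of which 20 and 18 lay in about its last megabase. The median Y peak of replicate 1 had 49.0% of its 36-base words on another chromosome and that of replicate 2 had 35.2%, a mean of 42.1% between the bounds set for the test, with replicate 1 close to the upper bound of 50%, so reads from shared sequence cannot be told apart from other sources. Of these peaks, 11 in each library had no such word. The bounds had been set for words found elsewhere in the assembly, while the count took words on other chromosomes alone. No biological explanation was tested.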
